A study of Drosophila melanogaster with 54 samples.

How the data were processed

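RNA was measured in 12 libraries of fly heads and histone H3K4me3 in 2 more. Per the labels' protocols, DNase-treated RNA was fragmented and dephosphorylated, and a linker was ligated to it before library preparation went on. The labels name the molecule as polyA RNA and the assay as sequencing of 3' ends. The RNA table holds counts of reads per gene and library as the authors deposited them, whole numbers that are not normalized. Per the submitters' processing notes, STAR and TopHat2 are named for the RNA libraries, Bowtie2 for the H3K4me3 libraries, and dm3 as the genome build of both; versions, the read counter, its annotation and its strand setting were not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and 132 tested genes had counts nearly equal to those of another gene (within 5% or 2 counts in every library, with at least 100 counts in all). The peak lists hold one deposited score per peak from the authors' caller, whose peak names begin with MACS, and peaks were given per library. Scores were used only to rank and describe peaks within a list.

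Groups and replicate numbers were taken from the labels, with 4 groups of 3 RNA libraries. Gene symbols were matched to a RefSeq table of the Release 6 assembly for names only: 12673 of 16719 matched directly, 3900 through a synonym and 146 not at all. No coordinates of that assembly were used. Every row named a gene and every count column belonged to a listed sample.

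Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by TMM, and 1 quasi-likelihood model with the 4 groups was fitted to all 12 libraries, so that the groups share an estimate of the spread. Tested were 29 °C against 18 °C in each genotype and over both, knockdown against control at each temperature, and the interaction (the temperature log2 fold change in knockdown flies minus that in control flies). P-values were adjusted by Benjamini-Hochberg over 9056 genes, with a threshold of 0.05, and the SE of a log2 fold change was taken from its F statistic. CPM values use the TMM-scaled library sizes. A level of 0 was bounded with 3 counts. Intervals of count ratios are 95% intervals for counting error only, and reads without molecular identifiers are not independent molecules. The interval of the summed receptor and Snmp1 genes is a 95% t interval from the spread between libraries within groups.

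The design fixed before the data were examined held 31 gene lists, of which 29 had at least 3 measured members and were tested with camera in limma 3.58.1 (preset correlation 0.01, then an estimated correlation) and with fry, on log CPM with a prior count of 2. Camera compares a list with other genes, and fry tests whether its genes move on balance one way. Camera called 9 lists for temperature in control flies, 11 in knockdown flies, 3 for knockdown at 18 °C, 9 at 29 °C, 6 for the interaction and 12 for temperature over both genotypes; with an estimated correlation the heat shock list alone was called, in the 3 temperature tests. Fry called 21, 18, 10, 10, 0 and 23 lists. The lists cover insulator proteins, visible markers, RNA interference, heat shock, the unfolded protein response, cold and stress response, the clock, immune peptides, phototransduction, neurons, neuropeptides, glia, female- and male-biased genes, fat body, sugar digestion, gut proteases, muscle, ovary and eggshell, accessory gland and testis, cytosolic and mitochondrial ribosomes, the respiratory chain, the mitochondrial genome, P450s, glutathione S-transferases, UDP-glycosyltransferases, odorant-binding proteins, cuticle, histones, and DNA repair with the cell cycle. Gut proteases had 1 measured member (Ser7, not called in any comparison) and the mitochondrial genome none, so neither was tested.

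Genes named in the text follow a rule of that design: BEAF-32 everywhere; per comparison up to 8 genes with the largest positive and 8 with the largest negative log2 fold change among those past the threshold with a mean of at least 5 CPM and no overlap between the groups (no overlap rule for the interaction); and per list up to 4 members past the threshold with the smallest adjusted p, or 1 with the highest mean where none passed. A gene named in 1 comparison may be given in others. The dosage compensation and odorant-binding values per library, Act88F per library, and the gene Orco were chosen after their values were seen.

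The model was tested on simulated counts with the real library sizes and 1 mean per gene over all 12 libraries. In each comparison 66 or 67 genes were changed per fold size, far fewer than were called in the real temperature and knockdown comparisons. The shares recovered are therefore rough and need not hold for the real data. For temperature in control flies it recovered 65.7%, 86.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold among 8942 genes; for temperature in knockdown flies 49.3%, 79.1% and 97% among 8930; for knockdown at 18 °C 53.7%, 88.1% and 95.5% among 8951; for knockdown at 29 °C 71.6%, 65.7% and 93.9% among 8936; and for the interaction 25.4%, 77.6% and 92.4% among 8933. Of the calls made, 4.46% to 7.8% were false. The share recovered at 1.5-fold was lowest for the interaction.

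Replicates were compared before use: no pair of libraries within a group differed by as little as sampling noise (chi-square per gene 3.57 to 14.7), so all were kept. Peak lists were compared with bedtools 2.31.1 with a minimum overlap of 1 bp. Alternatives were another scaling (the size factors of DESeq2 1.42.0 in edgeR), DESeq2 itself, no filter, thinning to the lowest total, a fold minimum of 2, only the libraries compared, the replicate number as a block, each library left out in turn, and other overlap rules for peaks; 3 more were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Motif searches in promoters and the assignment of peaks to genes need a dm3 genome and annotation, which were not used here.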

Results

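The series holds 54 samples from heads of Drosophila melanogaster, most of them libraries that mark the ends of transcripts at several temperatures and times of day. Processed data were used for 14 of them, and the other 40 were not analysed here. The 12 RNA libraries formed a 2-factor experiment on BEAF-32, a DNA-binding protein of chromatin boundaries (insulators), and its part in the response of the head transcriptome to a warm environment. The labels give YW as the strain of both genotypes. Control flies, whose genotype label is wild type and whose count columns are named WT, carried the actin5C-gal4 driver alone. Knockdown flies expressed a BEAF-32 RNA interference construct under the same ubiquitous driver. Both were raised at 25 °C and then held for 3 days as young adults at 18 °C or 29 °C in 12 h of light and 12 h of dark, with 3 libraries per genotype and temperature. The other 2 libraries were H3K4me3 chromatin immunoprecipitations from heads of Canton S, a wild-type strain, kept at 25 °C.

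Total counts per RNA library ran from 2905211 to 7146191. By replicate they were 5058802, 7146191 and 3588440 in control flies at 18 °C, 5184789, 4995229 and 5300995 in control flies at 29 °C, 3753206, 2905211 and 4250060 in knockdown flies at 18 °C, and 5858151, 6393926 and 4157130 in knockdown flies at 29 °C. A count of 0 in a library allowed a level of up to 0.42 to 1.03 CPM, the count relative to the library total, taking 3 counts as the limit and counting error alone. Of 16719 genes in the table, 3044 had no read in any library and 9056 had enough reads to be tested. Libraries of a group correlated across genes at r = 0.978 to 0.988 on log CPM, and the first principal component, with 44.4% of the variance, separated the temperatures while the second, with 23.2%, separated the genotypes. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values below are group means ± SD over 3 libraries, and adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

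BEAF-32 transcripts were strongly reduced in knockdown heads at both temperatures. At 18 °C they stood at 35.3 ± 3.52 CPM in control flies and 2.61 ± 0.943 CPM in knockdown flies, which left 7.39% (log2 fold change -3.70, SE 0.236, edgeR adjusted p = 5.43e-10). At 29 °C they stood at 34.5 ± 1.47 and 1.97 ± 1.26 CPM, which left 5.71% (16-fold lower, SE of the log2 fold change 0.227, edgeR adjusted p = 1.25e-10). All 6 knockdown libraries lay between 0.516 and 3.5 CPM and all 6 control libraries between 32.2 and 39.1 CPM. Temperature left no detectable difference in BEAF-32 in control flies (log2 fold change -0.02, SE 0.143, edgeR adjusted p = 0.931) or in knockdown flies (log2 fold change -0.31, SE 0.392, edgeR adjusted p = 0.569).

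**Figure D1:**
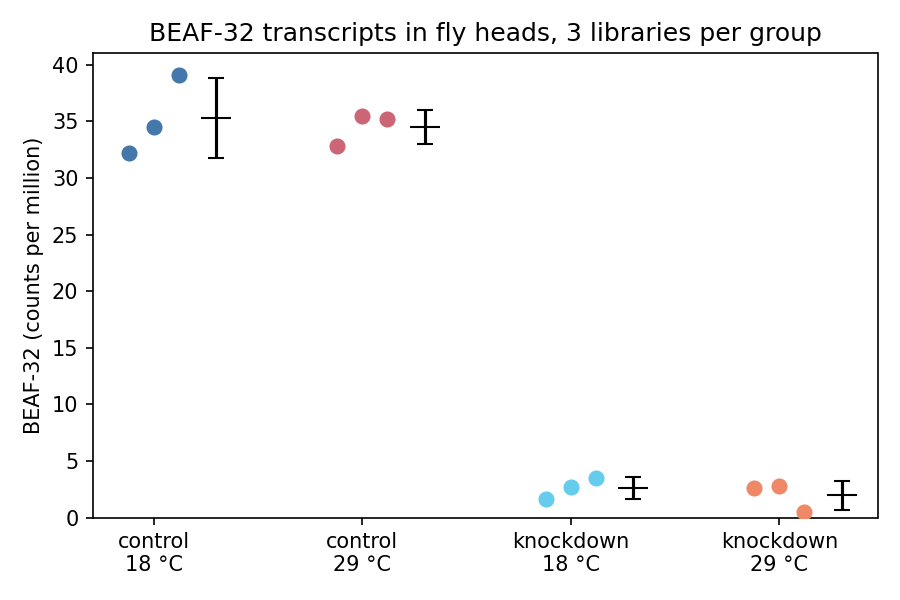
BEAF-32 transcript level in CPM for each of the 12 head RNA libraries (points), with the mean and SD of the 3 libraries of each group (bars). The control libraries sit between 32.2 and 39.1 and the knockdown libraries between 0.516 and 3.5.

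The first comparison asked how the head transcriptome of control flies differed between 29 °C and 18 °C. Most heat shock and ribosomal protein genes were higher in the warm, while most antimicrobial peptide, cuticle, muscle, glial and respiratory chain genes were lower. Lsp1beta, a larval serum storage protein, rose 36.1-fold, from 8.65 ± 2.33 to 321 ± 119 CPM (edgeR adjusted p = 3.02e-12). Hsp22, a small heat shock protein of mitochondria, rose 16.3-fold, from 3.87 ± 1.73 to 68.4 ± 16.9 CPM (edgeR adjusted p = 3.23e-11), a value it shares with the overlapping gene Hsp67Bb, whose reads could not be told apart from it. CG7214 fell from 2255 ± 816 to 11.5 ± 14.2 CPM (edgeR adjusted p = 4.49e-11), and Acp1, an adult cuticle protein that shares reads with CG31904, fell from 3674 ± 1360 to 86.6 ± 55.7 CPM (edgeR adjusted p = 2.09e-10). In all, 3440 of 9056 genes passed the test, 1646 raised and 1794 lowered, and 660 of them changed at least 2-fold. The 3 libraries at 29 °C lay wholly above or below those at 18 °C for 49.1% of genes, where chance gives 10%.

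Of 21 measured heat shock and chaperone genes, 16 rose in control flies and 0 fell (16 and 0 when adjusted over the list alone). The list's median log2 fold change was 0.96 and it stood apart from other genes (camera adjusted p = 8.29e-10), also with an estimated correlation between its genes (adjusted p = 0.0342). Hsp23 went from 7.55 ± 1.57 to 41.6 ± 0.371 CPM and the co-chaperone Hop from 44.5 ± 5.76 to 102 ± 11.5 CPM. Of 11 genes of the unfolded protein response 3 rose and 1 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.432). The raised ones were 1 without control 18 °C replicates 1 or 3 or control 29 °C replicate 1, Xbp1 also losing its call without control 29 °C replicates 2 or 3 (edgeR adjusted p = 0.0536 and 0.0613). The lowered gene ERp60 kept its call only without knockdown 18 °C replicates 1 or 3 or control 29 °C replicate 2, and without any other library its edgeR adjusted p was 0.053 to 0.178. DESeq2 gave 0.054. Cytosolic ribosomal protein genes moved together, with 80 of 84 raised and 0 lowered (81 and 0 adjusted over the list alone), a median of 0.56 and RpS20 rising 2.02-fold (camera adjusted p = 1.04e-29, adjusted p = 0.304 with an estimated correlation). Among the 29 phototransduction and photoreceptor genes 15 rose and 8 fell (17 and 8 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.365 with an estimated correlation), the lowered ones being 5 without control 18 °C replicate 1 or replicate 3. The light-activated channel gene trpl rose 2.62-fold to 1452 ± 39 CPM and norpA, the phospholipase C of the fly eye, rose 2.23-fold. Of 6 measured histone genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0698), with His4r 1.53-fold higher; His1:CG33834 lost its call without control 18 °C replicate 2 (edgeR adjusted p = 0.0982).

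Of 26 antimicrobial peptide and immune recognition genes, 15 fell in the warm and 0 rose in control flies (15 and 0 adjusted over the list alone), with a median log2 fold change of -1.18 (camera adjusted p = 9.35e-05, adjusted p = 0.367 with an estimated correlation). AttC, an attacin, fell from 293 ± 190 to 23.3 ± 10.4 CPM and Dro, drosocin, from 83.6 ± 85.2 to 3.37 ± 1.5 CPM. The 3 control libraries at 18 °C were far apart for these genes, with Dro at 15.2, 56.6 and 179 CPM. Of 33 cuticle protein genes 23 fell and 2 rose (24 and 2 adjusted over the list alone; camera adjusted p = 1.03e-05, adjusted p = 0.136 with an estimated correlation). Cpr62Bb fell 4.26-fold, against Cpr72Ec, which rose 9.53-fold to 606 ± 77 CPM. Of 13 glial genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.000214, adjusted p = 0.136 with an estimated correlation). Gat, the glial GABA transporter, was 2.09-fold lower and Eaat1, a glutamate transporter, 1.67-fold lower.

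Most muscle and respiratory chain genes were also lower at 29 °C in control heads. Of 21 muscle genes 15 fell and 2 rose (15 and 2 adjusted over the list alone), with a median log2 fold change of -0.72 (camera adjusted p = 8.63e-09, adjusted p = 0.226 with an estimated correlation). Prm, paramyosin, fell 2.63-fold and Zasp66 1.98-fold. Act88F, an actin of flight muscle, stood at 211 CPM in control 29 °C replicate 2 and at 7.96 CPM or less in the other 11 libraries. Of 66 nuclear-encoded respiratory chain genes 57 fell and 1 rose (59 and 2 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 4.77e-18, adjusted p = 0.365 with an estimated correlation). ATPsynbeta fell from 2369 ± 237 to 1355 ± 10.8 CPM and SdhB from 314 ± 17.7 to 181 ± 5.61 CPM. Of 73 mitochondrial ribosomal protein genes 14 rose and 9 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.432). The raised ones were 8 without control 18 °C replicate 2 and 9 without control 29 °C replicate 1 or 2, and the lowered ones 5 without control 18 °C replicate 1.

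Of 18 circadian clock genes 9 fell and 4 rose in control flies (10 and 4 adjusted over the list alone; camera adjusted p = 0.0628). The core repressor genes tim and per fell 2.6-fold and 2.17-fold, vri fell 2.17-fold, and Clk, which encodes their activator, rose 3.67-fold to 8.125 ± 0.465 CPM. The time of day of collection was not given for these libraries. Of 6 cold and stress response genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.000823, adjusted p = 0.136 with an estimated correlation). They included the Turandot stress peptide genes TotC, 4.9-fold lower, and TotA, 2.27-fold lower. Among 29 neuropeptide and processing genes 8 rose and 8 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.885), with Nplp3 4.12-fold lower and Dsk, drosulfakinin, 2.36-fold higher. The 23 neuronal genes split into 5 raised and 6 lowered (5 and 6 adjusted over the list alone; camera adjusted p = 0.885), Gad1 being 1.55-fold lower and elav 1.49-fold higher.

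Among genes of metabolism in control flies, 24 of 66 cytochrome P450 genes fell and 11 rose (26 and 11 adjusted over the list alone; camera adjusted p = 0.0698), Cyp6d5 falling 2.73-fold; without control 29 °C replicate 2 only 7 rose. Of 29 glutathione S-transferase genes 10 fell and 6 rose (10 and 6 adjusted over the list alone; camera adjusted p = 0.432), and of 8 UDP-glycosyltransferase genes 3 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.185), the raised gene Ugt86Dd losing its call without control 29 °C replicate 3 (edgeR adjusted p = 0.0986). Of 15 fat body and storage genes 6 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.303), with the storage protein Lsp2 12.1-fold lower, opposite to Lsp1beta. Sugar, starch and lipid digestion genes numbered 3 raised and 3 lowered of 10 (3 and 3 adjusted over the list alone; camera adjusted p = 0.746). Of 22 DNA repair and cell cycle genes 6 fell and 3 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.455, downward, while the median log2 fold change was 0.02 and the mean -0.37), the replication genes dup and PCNA falling 4.55-fold and 5.97-fold.

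Sex-biased markers differed between the temperatures and between libraries. Of 5 genes with male-biased expression 3 rose at 29 °C in control flies (3 adjusted over the list alone; camera adjusted p = 0.0714), among them roX2, an RNA of the male dosage compensation complex, from 10.9 ± 5.85 to 64.6 ± 10.3 CPM. Of the 4 genes with female-biased expression in the head, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.455), with fit 6.17-fold lower. The other lowered gene, Yp2, lost its call without control 18 °C replicate 2 or control 29 °C replicate 2 or 3 (edgeR adjusted p = 0.272, 0.0776 and 0.0764). The raised male-biased gene roX1 did so without control 18 °C replicates 2 or 3, control 29 °C replicates 2 or 3, or knockdown 29 °C replicate 3 (edgeR adjusted p = 0.184, 0.0553, 0.0993, 0.114 and 0.0524). The sex of the flies was not stated. Control 18 °C replicate 2 had the lowest roX1 of its group, 54.2 CPM against 191 and 143 CPM, and knockdown 29 °C replicate 1 the lowest of its own, 113 CPM against 257 and 205 CPM. Without those 2 libraries 3090 genes passed in control flies and 2751 in knockdown flies, an analysis chosen after the data were seen.

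The same comparison in knockdown flies asked whether the warm response was present when BEAF-32 was depleted. The largest responses again included Lsp1beta, which rose from 2.97 ± 0.781 to 296 ± 64.3 CPM (edgeR adjusted p = 1.71e-12), Hsp23, which rose 7.29-fold (edgeR adjusted p = 2.45e-12), CG7214, which fell from 579 ± 18.6 to 6.51 ± 2.17 CPM (edgeR adjusted p = 9.41e-10), and Crys, a lens protein gene, which fell 16.4-fold (edgeR adjusted p = 6.56e-11). In all, 3216 of 9056 genes passed, 1507 raised and 1709 lowered, and 655 of them changed at least 2-fold. For 45.1% of genes the 2 groups of libraries did not overlap, where chance gives 10%. Without control 29 °C replicate 1 and knockdown 18 °C replicates 2 and 3, which were high in odorant-binding genes, 1854 genes passed in this comparison. That setting was chosen after the data were seen and leaves knockdown flies at 18 °C with 1 library, assumed to vary like the others.

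Heat shock genes rose in knockdown flies at 17 of 21 and fell at 0 (17 and 0 adjusted over the list alone), with a median log2 fold change of 1.20 (camera adjusted p = 1.25e-12, adjusted p = 0.014 with an estimated correlation). Ribosomal protein genes rose at 81 of 84 and fell at 0 (81 and 0 adjusted over the list alone; median 0.67, camera adjusted p = 1.95e-37, adjusted p = 0.238 with an estimated correlation). Mitochondrial ribosomal protein genes rose at 31 of 73 and fell at 3 (32 and 3 adjusted over the list alone; camera adjusted p = 4.88e-05, adjusted p = 0.238 with an estimated correlation), mRpL53 and mRpL49 by 1.82-fold and 1.88-fold; mRpL53 shares reads with CG33155. Respiratory chain genes fell at 16 of 66 and rose at 4 (16 and 4 adjusted over the list alone; median -0.12, camera adjusted p = 0.0781). ATPsynbeta fell 1.54-fold and ND-PDSW rose 1.41-fold; 10 fell without knockdown 18 °C replicate 1 or knockdown 29 °C replicate 3. Muscle genes fell at 16 of 21 and rose at 0 (17 and 0 adjusted over the list alone; median -0.93, camera adjusted p = 2.07e-10, adjusted p = 0.214 with an estimated correlation), Mf by 1.99-fold and Prm by 2.48-fold.

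Antimicrobial and immune genes fell at 18 of 26 in the warm in knockdown flies and rose at 0 (18 and 1 adjusted over the list alone; camera adjusted p = 5.12e-05, adjusted p = 0.34 with an estimated correlation). Drs, drosomycin, fell from 1075 ± 697 to 104 ± 43.1 CPM and IM1, a bomanin, from 2279 ± 947 to 756 ± 167 CPM, and without knockdown 18 °C replicate 3 the list had 11 lowered genes. Glial genes fell at 10 of 13 and rose at 1 (11 and 1 adjusted over the list alone; camera adjusted p = 5.12e-05, adjusted p = 0.0696 with an estimated correlation), the astrocyte gene alrm by 1.98-fold. Clock genes fell at 7 of 18 and rose at 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00143, adjusted p = 0.0696 with an estimated correlation), tim by 2.69-fold, per by 2.31-fold and vri by 2.55-fold. Cuticle genes fell at 20 of 33 and rose at 3 (21 and 4 adjusted over the list alone; camera adjusted p = 4.51e-05, adjusted p = 0.163 with an estimated correlation). Phototransduction genes rose at 14 of 29 and fell at 7 (14 and 8 adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.448 with an estimated correlation), norpA by 2.35-fold and trpl by 1.88-fold. Histone genes rose at 4 of 6 (4 adjusted over the list alone, camera adjusted p = 0.0413, adjusted p = 0.214 with an estimated correlation). Odorant-binding and chemosensory genes fell at 20 of 34 and rose at 8 (20 and 8 adjusted over the list alone, camera adjusted p = 0.00712, adjusted p = 0.34 with an estimated correlation). Some genes of that list, Os-C among them, were highest in knockdown 18 °C replicates 2 and 3.

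The temperature responses of the genotypes overlapped widely. Of the genes raised by warmth, 1023 were called in both, against 274 for independent lists of these lengths, and of the lowered genes 1198 were called in both, against 339. The 2 comparisons share no library. Lsp1beta, Hsp22, Hsp23, tim, per, trpl, norpA, Prm and Gat were among the genes called in the same direction in both. Across genes the log2 fold changes correlated at Pearson r = 0.673 and Spearman rho = 0.726, where genes are not independent replicates. The 31 genes called in opposite directions included smp-30 and y, described with the interaction.

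**Figure D2:**
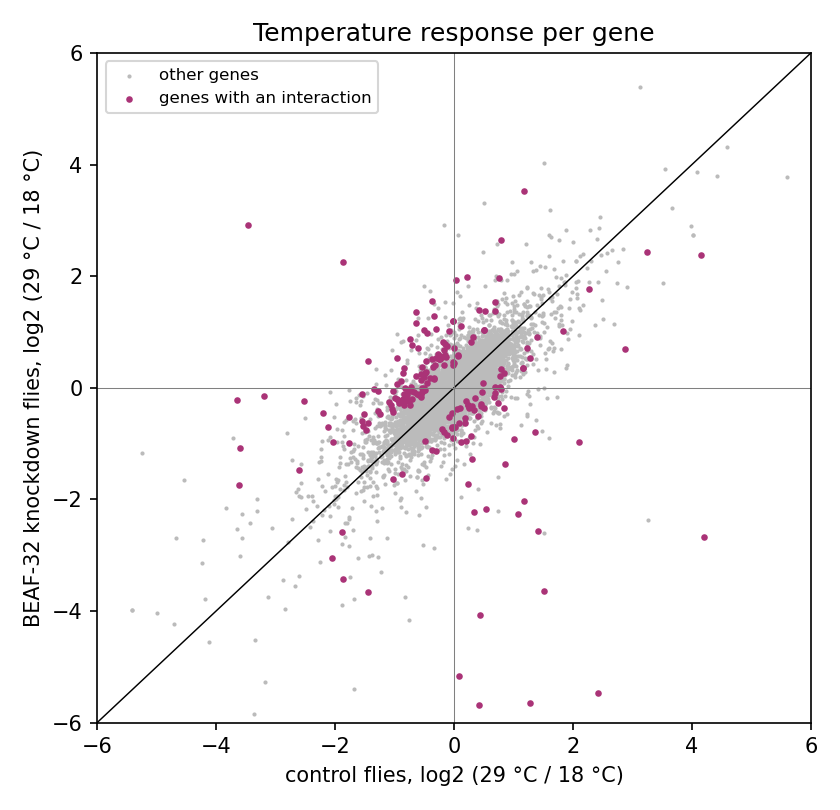
Log2 fold change from 18 °C to 29 °C for each of the 9056 tested genes in control flies (horizontal) and BEAF-32 knockdown flies (vertical), with the line of equal response; 7 genes lie outside the plotted range of 6. The 209 genes with an interaction between genotype and temperature are coloured. They lie away from the line by selection, since the interaction is the distance from it. Across all tested genes Pearson r was 0.673.

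The knockdown comparison at 18 °C asked which transcripts differed with BEAF-32 depleted in the cold. CG11313 was nearly silent in control flies, with 2 counts in all 3 libraries, and stood at 71.1 ± 1.25 CPM in knockdown flies, a ratio of 590 with a counting interval of 163 to 4880. CG30083 went the other way, from 10.5 ± 0.642 to 0.275 ± 0.0591 CPM, where 3 counts remained and the ratio was 39.4 with an interval of 13.3 to 193. CG3397 fell 29.2-fold, from 28.9 ± 5.49 to 0.938 ± 0.634 CPM (edgeR adjusted p = 2.5e-10), and phr, a DNA photolyase whose reads could not be separated from CG18853, fell 10.8-fold (edgeR adjusted p = 4.2e-08). In all, 1279 genes passed, 600 raised and 679 lowered, of which 297 changed at least 2-fold, and the groups did not overlap for 28.8% of genes, where chance gives 10%. Without the 3 libraries high in odorant-binding genes, 2 of them knockdown libraries of this comparison, 559 genes passed, 521 of them also called with all libraries.

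Of 26 antimicrobial and immune genes 15 rose in knockdown flies at 18 °C and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 1.05 (camera adjusted p = 1.94e-08, adjusted p = 0.475 with an estimated correlation). AttA, an attacin, rose 27.2-fold, from 3.46 ± 2.84 to 100.8 ± 72.4 CPM (edgeR adjusted p = 4.99e-07), and IM1 and IM3 rose 2.44-fold and 1.75-fold. PGRP-LB, an amidase that degrades peptidoglycan, rose 2.05-fold (edgeR adjusted p = 0.000195). Without knockdown 18 °C replicate 3 the list had 9 raised genes. All 4 female-biased genes rose (4 adjusted over the list alone; camera adjusted p = 0.00744, adjusted p = 0.475 with an estimated correlation), the yolk protein genes Yp1, Yp2 and Yp3 by 1.64-fold, 1.8-fold and 1.51-fold and fit by 1.83-fold. These calls were fragile. Without knockdown 18 °C replicate 2 they were lost for Yp1, Yp2 and Yp3 (edgeR adjusted p = 0.0665, 0.0545 and 0.116), without control 18 °C replicate 1 for Yp1 and Yp3 (0.0701 and 0.122), without knockdown 18 °C replicate 1 and control 18 °C replicate 3 for Yp3 (0.052 and 0.0552), and by DESeq2 for Yp1, Yp3 and fit (0.0655, 0.101 and 0.0776). Of 5 male-biased genes edgeR and DESeq2 called 0, with 1 at an unadjusted p under 0.05 (1 lowered adjusted over the list alone; camera adjusted p = 0.498).

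Of 15 fat body and storage genes 6 fell and 2 rose in knockdown flies at 18 °C (8 and 2 adjusted over the list alone; camera adjusted p = 0.00385, adjusted p = 0.475 with an estimated correlation). Lsd-1, a perilipin of lipid droplets, fell 2.14-fold to 119 ± 12.9 CPM, AkhR, the receptor of adipokinetic hormone, fell 3.07-fold, and Obp99b fell 4.3-fold. Of 10 sugar and digestion genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.116). The glucosidase gene tobi was 4.93-fold lower. The other calls were fragile, and 1 gene fell without control 18 °C replicate 3 or knockdown 18 °C replicates 2 or 3. Amy-d lost its call without knockdown 18 °C replicates 1, 2 or 3 or control 18 °C replicate 3 (edgeR adjusted p = 0.0534, 0.1, 0.105 and 0.167). LManII lost it without knockdown 18 °C replicates 2 or 3 or control 18 °C replicates 1, 2 or 3 (0.0753, 0.189, 0.054, 0.0575 and 0.141) or with the replicate number as a block (0.059). The raised Mal-B1 lost it without knockdown 18 °C replicate 1 or control 18 °C replicate 2 (0.102 and 0.0784). P450 genes numbered 16 lowered and 7 raised of 66 (19 and 10 adjusted over the list alone; camera adjusted p = 0.0611). Cyp6a23 was 5.31-fold lower and Cyp6a17 2.15-fold higher. Ugt86Dd fell 5.92-fold, from 57.5 ± 1.58 to 9.79 ± 0.858 CPM (edgeR adjusted p = 8.69e-12). TotX and TotA fell 4.33-fold and 2.19-fold, while TotM rose 2.27-fold.

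In the eye, Rh6, the rhodopsin of a class of inner photoreceptors, fell 4.25-fold from 213 ± 20.6 to 50.5 ± 8.29 CPM (edgeR adjusted p = 1.24e-11), while Rh5, the rhodopsin of the alternative class, rose 2.05-fold to 449 ± 26.6 CPM (edgeR adjusted p = 5.27e-09). The whole phototransduction list had 8 raised and 4 lowered of 29 (8 and 5 adjusted over the list alone; camera adjusted p = 0.39), with 5 raised without knockdown 18 °C replicate 1 or 2. Of 8 visible marker genes, several of them for eye pigment, 3 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.564, downward, with a median of 0.14 and a mean of -0.11). Among them se and bw were 2.34-fold and 2.2-fold lower and v 1.61-fold higher. The third lowered gene, st, lost its call without knockdown 18 °C replicates 1, 2 or 3 or control 18 °C replicates 1 or 3 (edgeR adjusted p = 0.0753, 0.0589, 0.0755, 0.0514 and 0.0745) and by DESeq2 (0.0851). Among 16 insulator and promoter-binding protein genes, BEAF-32 and su(Hw) fell and CTCF and row rose (2 and 2 adjusted over the list alone; camera adjusted p = 0.78, upward, with a median of 0.15 and a mean of -0.13). The calls other than BEAF-32 were fragile. CTCF lost its call without knockdown 18 °C replicates 1 or 3 or control 18 °C replicates 1 or 3 (edgeR adjusted p = 0.0865, 0.126, 0.125 and 0.106). For row this held without knockdown 18 °C replicates 2 or 3 or control 18 °C replicate 2 (0.0639, 0.053 and 0.0566), and for su(Hw) without knockdown 18 °C replicates 1 or 3 or control 18 °C replicates 2 or 3 (0.0967, 0.161, 0.0804 and 0.116). Of 21 heat shock genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.761). The raised l(2)efl was 1.71-fold higher and Hsp83 1.41-fold lower. Hsc70-5 lost its call without knockdown 18 °C replicates 1 or 3 or control 18 °C replicates 1 or 3 (edgeR adjusted p = 0.0703, 0.0924, 0.0824 and 0.0735). Of 8 RNA interference genes AGO2 alone was called, 1.23-fold lower (1 adjusted over the list alone; camera adjusted p = 0.564). It lost its call without knockdown 18 °C replicates 1, 2 or 3 or control 18 °C replicate 2 (edgeR adjusted p = 0.0909, 0.0756, 0.0854 and 0.212).

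The knockdown comparison at 29 °C asked the same in the warm. CG11313 had no count in the 3 control libraries and stood at 48.5 ± 11.5 CPM in knockdown flies, at least 253-fold higher against a limit of 3 counts over the group. Dro rose from 3.37 ± 1.5 to 125.5 ± 68.3 CPM (36.9-fold, edgeR adjusted p = 4.48e-05), DptB, a diptericin, from 5.64 ± 0.581 to 122 ± 54.5 CPM (21.8-fold, edgeR adjusted p = 8.79e-06), and y, the body pigment gene yellow, from 0.646 ± 0.389 to 19.6 ± 4.15 CPM (28.9-fold, edgeR adjusted p = 1.34e-09). CG3397, CG30083 and CG13044 fell 28.1-fold, 23.9-fold and 23.3-fold. Act88F also passed, with a log2 fold change of -6.16, but this rested on control 29 °C replicate 2, without which the value was -1.46 (edgeR adjusted p = 0.153). In all, 1332 genes passed, 647 raised and 685 lowered, and 269 of them changed at least 2-fold. Groups did not overlap for 31.8% of genes, where chance gives 10%. Without control 29 °C replicate 3 the count was 873.

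Antimicrobial and immune genes rose at 9 of 26 at 29 °C and fell at 0 (12 and 0 adjusted over the list alone; median 1.28, camera adjusted p = 1.64e-07, adjusted p = 0.385 with an estimated correlation), AttA rising 36-fold and Def, defensin, 3.46-fold. Respiratory chain genes rose at 37 of 66 and fell at 0 (52 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 4.09e-19, adjusted p = 0.44 with an estimated correlation). ND-49 rose 1.43-fold and COX7C 1.37-fold. Without control 29 °C replicate 3 the raised ones were 18, without knockdown 29 °C replicate 1 they were 22 and without knockdown 29 °C replicate 3 they were 24. Mitochondrial ribosomal protein genes rose at 12 of 73 and fell at 1 (12 and 1 adjusted over the list alone; camera adjusted p = 9.74e-05, adjusted p = 0.385 with an estimated correlation), a count that was 3 without control 29 °C replicate 3, 7 without control 29 °C replicate 2, and 5, 6 and 7 without knockdown 29 °C replicates 1, 2 and 3. Cytosolic ribosomal protein genes rose at 8 of 84 and fell at 1 (4 and 0 adjusted over the list alone; camera adjusted p = 1.35e-05, adjusted p = 0.732 with an estimated correlation), and at 3, 0, 2 and 3 without control 29 °C replicates 2 and 3 and knockdown 29 °C replicates 1 and 3. Neuronal genes rose at 6 of 23 and fell at 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00127, adjusted p = 0.385 with an estimated correlation), Gad1 by 1.3-fold, and at 2, 3 and 3 without control 29 °C replicate 2 and knockdown 29 °C replicates 2 and 3. Of 11 genes of the unfolded protein response Xbp1 alone was called, 1.24-fold lower (1 adjusted over the list alone; camera adjusted p = 0.0862), and without knockdown 29 °C replicate 3 it was not (edgeR adjusted p = 0.0503). Hsp70Ba and Hsp70Bbb, near-identical copies between which reads may be divided, rose 4.42-fold and 3.69-fold, within a heat shock list of 6 raised and 2 lowered (8 and 5 adjusted over the list alone; camera adjusted p = 0.13).

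Among detoxification genes in knockdown flies at 29 °C, glutathione S-transferase genes fell at 7 of 29 and rose at 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00984, adjusted p = 0.155 with an estimated correlation), GstO3 by 1.46-fold; without knockdown 29 °C replicate 1 the lowered ones were 4. UDP-glycosyltransferase genes fell at 4 of 8 (5 adjusted over the list alone; camera adjusted p = 0.00355, adjusted p = 0.155 with an estimated correlation), Ugt86Dd by 3.85-fold. The list includes Ugt, a glucosyltransferase of the endoplasmic reticulum, which lost its call without knockdown 29 °C replicates 1 or 2 or control 29 °C replicates 1 or 3 (edgeR adjusted p = 0.115, 0.117, 0.115 and 0.112), and Ugt35a, which did so without knockdown 29 °C replicate 1 or control 29 °C replicate 1 (0.087 and 0.057). P450 genes fell at 18 of 66 and rose at 8 (24 and 11 adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.155 with an estimated correlation), Cyp6a23 and Cyp4s3 by 3.51-fold and 2.8-fold, and 5 rose without control 29 °C replicate 3. Female-biased genes rose at 2 of 4, fit by 3.24-fold (3 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.488 with an estimated correlation). Of 5 male-biased genes 1 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.294). Among photoreceptor genes Rh6 was 5.02-fold lower, Rh5 1.74-fold higher and trpl 1.79-fold lower. Fat body genes numbered 3 raised and 3 lowered of 15 (3 and 3 adjusted over the list alone; camera adjusted p = 0.616), with Lsp2 3.21-fold higher and Obp99b 5.53-fold lower.

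Between the temperatures, 228 genes were raised by knockdown at both, against 42.9 for independent lists, and 335 were lowered at both, against 51.4, while 16 were called in opposite directions. AttA, DptB, Dro, Rh5, v and fit were among the genes higher at both, and Rh6, TotX, TotA, Obp99b, Ugt86Dd, Cyp6a23, se, bw, CG3397 and CG30083 among those lower at both. These 2 comparisons share no library, and the log2 fold changes correlated across genes at r = 0.504 and rho = 0.428. Each genotype is a single line, so differences of line and of knockdown cannot be separated in any of these contrasts.

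**Figure D3:**
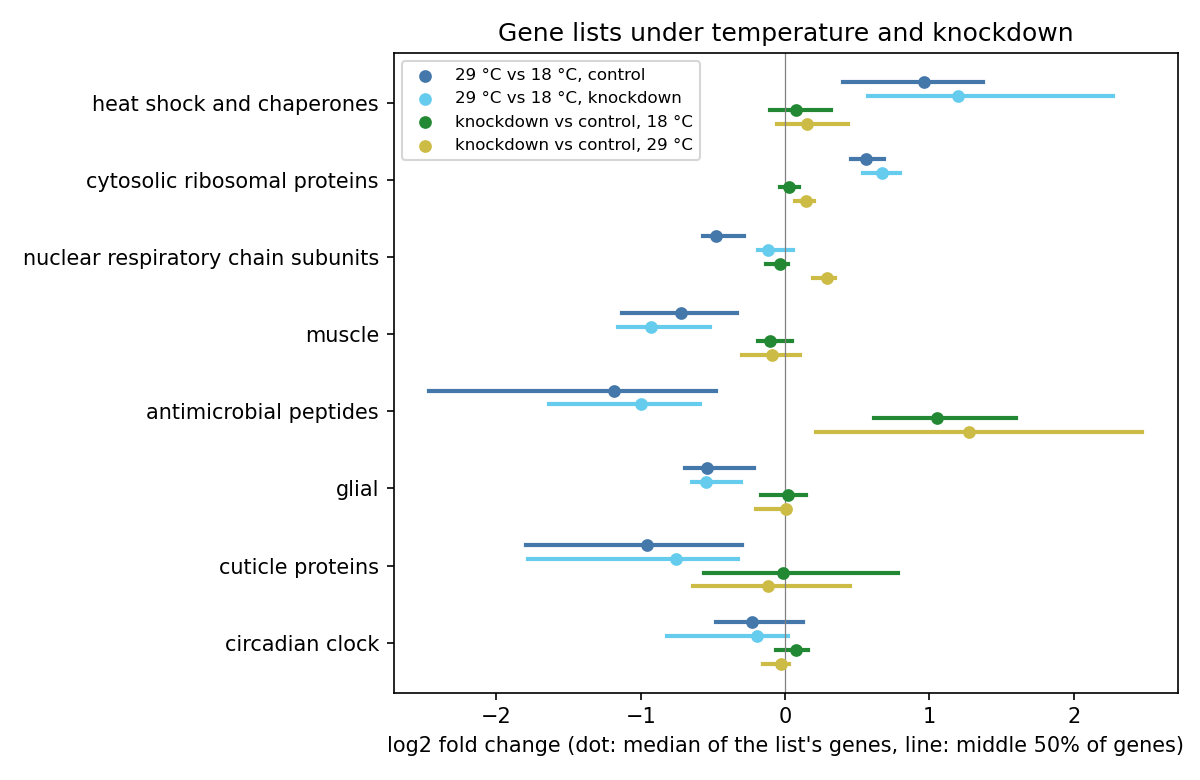
Median log2 fold change (dots) and the middle 50% of genes (lines) for 8 of the gene lists under each of 4 comparisons, warm against cold in each genotype and knockdown against control at each temperature. Heat shock genes lie right of 0 with temperature (medians 0.96 and 1.20), and antimicrobial genes lie left of 0 with temperature and right of 0 with knockdown (1.05 and 1.28).

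The central question was whether the response to warmth differed with BEAF-32 depleted, tested gene by gene as the interaction of genotype and temperature. The median response did not differ detectably. Across the 2194 genes raised by warmth over both genotypes the median log2 response was 0.48 in control and 0.48 in knockdown flies. The difference was 0.01, which limma's fry did not call. Across the 2309 lowered genes the medians were -0.50 and -0.49, a difference of 0.01, not called either. That difference became 0.03 and was called without control 18 °C replicate 2. The response was smaller in size in knockdown flies for 48.7% of raised and 51.7% of lowered genes. The slope through the origin of knockdown on control responses was 0.899 for raised and 0.818 for lowered genes, and was not tested. Noise in the control values pulls such a slope below that of equal responses, so it does not measure a weaker response. Single genes did differ, and 209 of 9056 had an interaction, 126 positive and 83 negative, with 73 at least 2-fold. DESeq2 called 215, of which 71.2% were positive against 60.3% by edgeR. The count was 122 without control 29 °C replicate 3, 138 without knockdown 29 °C replicate 3, and 80 without the 3 libraries high in odorant-binding genes. It was 423 without the filter on low counts.

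Several of these genes lost or reversed their temperature response in knockdown flies. CG8665 fell with warmth in control flies, from 51.5 ± 7.29 to 8.76 ± 1.9 CPM, and stood at 35.9 ± 2.59 and 30.8 ± 2.64 CPM in knockdown flies (interaction log2 2.30, SE 0.196, edgeR adjusted p = 1.28e-06). CG5999, also listed as the UDP-glycosyltransferase Ugt37A3, behaved alike, at 8.59 ± 0.581 and 0.639 ± 0.59 CPM in control and 7.96 ± 2.53 and 7.16 ± 2.18 CPM in knockdown flies (3.44, SE 0.529, edgeR adjusted p = 0.00066). smp-30, the fly regucalcin, fell in control flies from 94.8 ± 15.2 to 57.2 ± 1.68 CPM and rose in knockdown flies from 43.9 ± 3.29 to 79.8 ± 2.1 CPM (1.61, SE 0.144, edgeR adjusted p = 1.45e-06). y fell in control flies from 2.36 ± 0.487 to 0.646 ± 0.389 CPM and rose in knockdown flies from 4.18 ± 0.811 to 19.6 ± 4.15 CPM (4.11, SE 0.524, edgeR adjusted p = 0.000105). This gene is on the visible marker list, and a difference of line cannot be told apart from the knockdown here. Def had 52.6 ± 20.3 and 18.65 ± 1.63 CPM in control flies, a fall, and 46.5 ± 17.2 and 64.7 ± 3.15 CPM in knockdown flies (1.92, SE 0.308, edgeR adjusted p = 0.0011).

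Of the 209 genes, 61 were called with temperature in control flies alone, 64 in knockdown flies alone, 54 in both in the same direction and 30 in both in opposite directions. Of the 126 positive genes 90 were called lower in knockdown flies at 18 °C and 47 called higher at 29 °C. Of the 83 negative ones 50 were called higher at 18 °C and 36 lower at 29 °C. Lsd-1, a positive gene, was lower at 18 °C, at 254 ± 28.8 and 229 ± 24.8 CPM in control flies and 119 ± 12.9 and 205 ± 4.96 CPM in knockdown flies (0.93, SE 0.14, edgeR adjusted p = 0.000507). Cyp12d1-p and Cyp12d1-d, near-identical copies between which reads may be divided, had interactions of 1.93 and 2.00. Lsp2 and Hex-C also had positive interactions, of 2.52 and 0.52, and Obp99a of 1.87. Among negative genes, trpl had -0.48 and Cpr72Ec -0.81, their rise in the warm being smaller in knockdown flies, and CG13044 had -2.20, its fall being steeper. CG10924 rose with warmth in control flies and fell in knockdown flies, from 15.2 ± 4.28 to 8.06 ± 2.05 CPM (-3.08, SE 0.617, edgeR adjusted p = 0.00743).

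By list, all 66 respiratory chain genes had a positive interaction value, with a median of 0.36 (camera adjusted p = 2.61e-30, adjusted p = 0.489 with an estimated correlation). Of them 3 passed on their own and 46 when adjusted over the list alone. The calls were 33 without control 18 °C replicate 2, 29 by DESeq2, 24 without the filter and 6 after thinning. With DESeq2's size factors 1 gene passed, and with the replicate number as a block all 3 calls were lost. ND-B18, cype and COX7A were those 3, at 0.51, 0.46 and 0.44. All 3 lost their calls without any one of knockdown 18 °C replicate 3, knockdown 29 °C replicates 1, 2 or 3, control 18 °C replicates 1 or 3, and control 29 °C replicates 1 or 3 (edgeR adjusted p = 0.0516 to 0.152), and some of them without others. Mitochondrial ribosomal protein genes had 1 call of 73, mRpL49 (1 adjusted over the list alone; median 0.21, camera adjusted p = 1.42e-06, adjusted p = 0.489 with an estimated correlation). It was lost without knockdown 18 °C replicate 3, any knockdown 29 °C or control 29 °C library, or control 18 °C replicates 1 or 3 (edgeR adjusted p = 0.0544 to 0.15). Of 84 cytosolic ribosomal protein genes edgeR and DESeq2 called 0, and 0 had an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.00301, adjusted p = 0.965 with an estimated correlation). Fat body genes had 3 of 15 positive (4 positive and 1 negative adjusted over the list alone; camera adjusted p = 0.015, adjusted p = 0.489 with an estimated correlation), and sugar genes 1 of 10, Mal-B2 (3 adjusted over the list alone; camera adjusted p = 0.0118, adjusted p = 0.489 with an estimated correlation). Of 21 heat shock genes edgeR called 0 and DESeq2 1, with 8 at an unadjusted p under 0.05 (3 positive and 3 negative adjusted over the list alone; camera adjusted p = 0.226). Of 18 clock genes edgeR and DESeq2 called 0, with 4 at an unadjusted p under 0.05 (2 negative adjusted over the list alone; camera adjusted p = 0.0509).

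Odorant-binding and chemosensory genes gave the most negative interactions, 8 of 34 with 1 positive (12 and 3 adjusted over the list alone; camera adjusted p = 0.00953, adjusted p = 0.505 with an estimated correlation). Obp83a, Obp83b and a10, all expressed in the antenna, had -6.93, -7.88 and -6.88. The 8 negative calls became 3 without control 29 °C replicate 1 or knockdown 29 °C replicate 1, 4 without control 18 °C replicate 3 or knockdown 29 °C replicate 2, and 5 without control 18 °C replicate 1, knockdown 18 °C replicate 3 or knockdown 29 °C replicate 3. Obp83a lost its call without control 29 °C replicate 1, where it was -4.37 (edgeR adjusted p = 0.608), and also without knockdown 18 °C replicate 3, any knockdown 29 °C library or any control 18 °C library (edgeR adjusted p = 0.0563 to 0.0828). Obp83b lost its call without control 29 °C replicate 1, at -4.22 (edgeR adjusted p = 0.683), and without knockdown 29 °C replicate 1, at -7.43 (edgeR adjusted p = 0.0533). Os-C stood at 23.5, 30 and 24.5 CPM in control 29 °C replicate 1 and knockdown 18 °C replicates 2 and 3 and had no count in the other 9 libraries. The summed level of the 8 lowered genes was 12.9 ± 0.693 CPM in control flies at 18 °C and 17.6 ± 2.43 CPM in knockdown flies at 29 °C. It was 88.7, 19 and 16.5 CPM in control flies at 29 °C and 30.6, 274 and 186 CPM in knockdown flies at 18 °C, replicates 1 to 3.

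**Figure D4:**
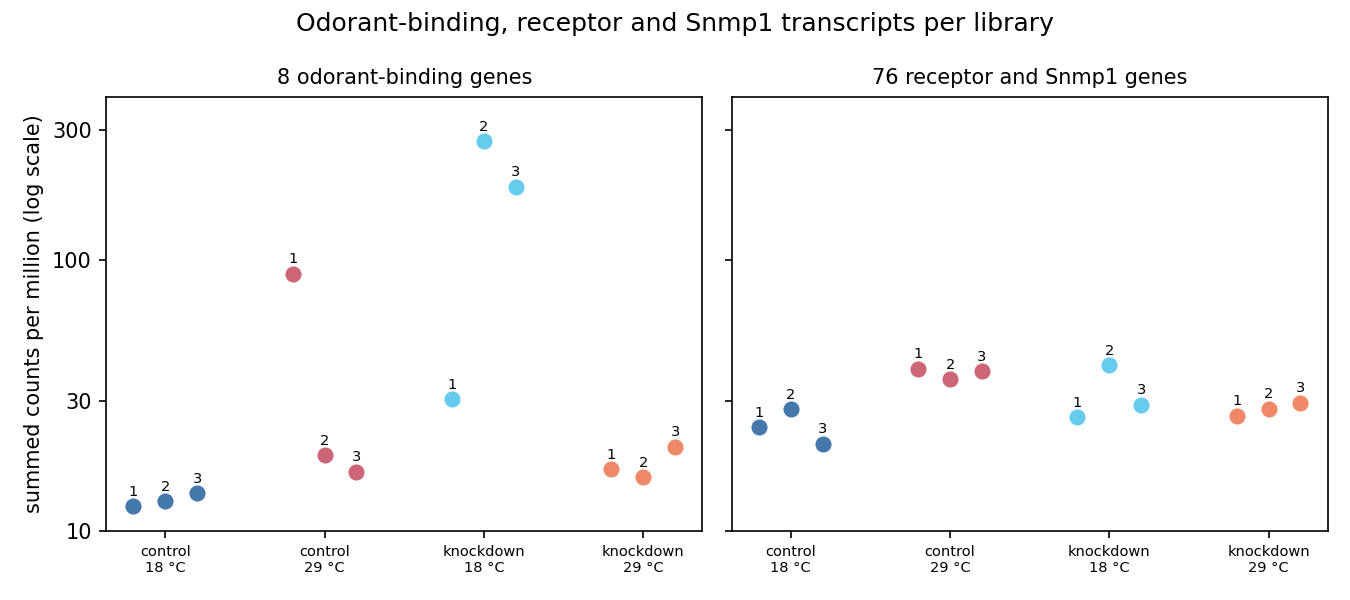
Summed CPM (log axis) of the 8 odorant-binding genes with a negative interaction (left) and of 76 genes outside that list, odorant and ionotropic receptors with Snmp1 (right), in each of the 12 libraries, with replicate numbers. The odorant-binding sum reaches 88.7, 274 and 186 in 3 libraries and stays at or below 30.6 in the other 9, while the sum of receptors and Snmp1 runs from 20.9 to 40.8.

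The H3K4me3 libraries mapped this histone mark in wild-type heads at 25 °C, as positions of the dm3 genome. The authors' lists held 4784 and 4526 peaks with median widths of 2622.5 and 2634 bp, covering 14.4 and 14.3 Mb. With an overlap of at least 1 bp, 4360 peaks of the first library (91.1%) and 4277 of the second (94.5%) were shared. With midpoints within 200 bp the shared peaks were 2828, or 59.1% and 62.5%. The covered bases had a Jaccard index of 0.784. Peaks by chromosome numbered 826 and 772 on 2L, 946 and 905 on 2R, 873 and 848 on 3L, 1093 and 1038 on 3R, 63 and 56 on 4, and 831 and 798 on X. The score of each peak is the authors' own, and its commonest value, 3100, was held by 48.4% and 47.8% of peaks. Over 3915 one-to-one pairs the scores had a Spearman rho of 0.70, and over the 1461 pairs below 3100 it was 0.434, across peaks, which are not independent replicates. Peaks without a partner, 424 and 249, had median scores of 142 and 111. With 1 group of 2 libraries there is no comparison between conditions.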

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

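Of the tests in this part, those of the immune genes, the comparison of respiratory chain with muscle genes, and, for the odorant-binding genes, leaving out 3 libraries and taking receptor genes and Snmp1 singly were chosen only after the result was seen. Each genotype was a single line, so line and knockdown cannot be told apart in any interaction. The interaction test asks whether the effect of temperature differed between the genotypes, and 209 genes met it. Among those with a mean of at least 5 CPM, the largest positive values were y with 4.11, CG5999 with 3.44, DptB with 3.04, Lsp2 with 2.52, CG4500 with 2.34, CG8665 with 2.30, Cyp12d1-d with 2.00 and Cyp12d1-p with 1.93. With the same limit and more than 3 counts in each group, the largest negative ones were Obp83b with -7.88, Obp83a with -6.93, a10 with -6.88, CG10924 with -3.08, OS9 with -2.55 and CG13044 with -2.20. DptB lost its call without knockdown 18 °C replicate 1, knockdown 29 °C replicate 2, control 18 °C replicate 3 or any control 29 °C library (edgeR adjusted p = 0.052 to 0.0915). CG4500 lost it without knockdown 18 °C replicates 1 or 2, knockdown 29 °C replicates 1 or 2, control 18 °C replicates 1 or 3, or control 29 °C replicate 3 (0.0548 to 0.096). OS9 lost it without control 29 °C replicate 1 (0.0551). Obp83b and Obp83a also lost theirs without control 29 °C replicate 1, at -4.22 and -4.37 (0.683 and 0.608), Obp83b without knockdown 29 °C replicate 1 (0.0533), and Obp83a without knockdown 18 °C replicate 3 or any knockdown 29 °C or control 18 °C library (0.0563 to 0.0828).

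Other splits of the libraries bear on how many genes grouping alone would call. For the interaction the real value was 209 and the highest of the other balanced splits 2, with 1 of 82 splits as large. The real value was also the largest for the 4503 genes changed over both genotypes (highest other 771, 1 of 60 drawn). It was the largest too for the 1023 genes raised in both genotypes (highest other 0, 1 of 100 splits). The same held for the 563 changed by knockdown at both temperatures (highest other 0, 1 of 100 splits). Those 100 are pairs of the 10 splits of each pairwise comparison. The other splits there called at most 3 genes, so their pairs could share hardly any. The 100 pairs therefore add nothing to the 10 splits. The other splits mix the real groups, which widens the spread within them and lowers their calls. The calls of the interaction and of temperature over both genotypes therefore follow the labelled grouping of these libraries. The splits cannot decide on chance differences between cultures. For the 4 pairwise comparisons the 10 splits are too few for a share under 0.05; the real values were 3440, 3216, 1279 and 1332 and the highest others 0, 0, 3 and 0, the real split alone (1 in each) reaching its value. For the difference in response size chance cannot be excluded: the median was 0.00962 for raised genes (largest other in size -0.0323, 52 of 82 splits as large) and 0.0131 for lowered genes (largest other in size 0.0394, 41 of 82 splits).

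Of 34 odorant-binding and chemosensory genes 8 had a negative interaction and 1, Obp99a, a positive one of 1.87; the median was -6.88 over these 9, which were chosen by their calls, and -0.24 over all 34. Leaving out libraries cannot decide on genes chosen with them in. Without control 29 °C replicate 1 the median of the called genes was -4.37 and the negative calls were 3. That library and knockdown 18 °C replicates 2 and 3 lay above all other 9 in 7 of the 9 genes. Without these 3 libraries, which leaves 1 library in knockdown flies at 18 °C, the median was -1.33 over 5 genes still tested. Obp8a and Obp99a, where the 3 libraries did not stand apart, kept their interactions. These were -1.55 and 1.85, against -1.15 and 1.87 with all libraries. An effect of BEAF-32 depletion that differs between libraries of 1 group stays open only for knockdown 18 °C replicates 2 and 3. Control 29 °C replicate 1 was also high, with BEAF-32 itself at 32.8 CPM, so depletion cannot account for that library. Varying amounts of antennal tissue between heads may be a source, and this stays open. The summed receptor and Snmp1 genes had an interaction of -0.82 (95% interval -1.36 to -0.278, from the spread between libraries), which includes the 2-fold change set as the bound. By replicate that sum was 39.6, 36.1 and 38.7 CPM in control flies at 29 °C and 26.2, 40.8 and 29.1 CPM in knockdown flies at 18 °C, and it stood at 20.9 to 38.7 CPM in the 9 libraries without an Os-C count, a level that would hide a small share. Of the 8 such genes with enough reads to be tested singly, Snmp1 included, all 8 had a negative value and 1 was called, Orco, the co-receptor of odorant receptors, named after its values were seen: it had 13 and 16 counts in control flies at 18 °C and 29 °C and 41 and 3 in knockdown flies (edgeR adjusted p = 0.0229), a call lost without control 18 °C replicates 1 or 3, control 29 °C replicate 1 or knockdown 29 °C replicates 1 or 2 (0.0517, 0.0502, 0.155, 0.0674 and 0.0786).

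Of 26 immune genes 21 were higher in knockdown flies at both temperatures, 5 of them called at both, and with an estimated correlation the list did not stand apart from other genes (adjusted p = 0.475 at 18 °C and 0.385 at 29 °C). A single library is argued against, since the lowest list median without any of the 12 libraries was 0.765 at 18 °C and 1 at 29 °C. A larger share of fat body is not decided. The female-biased head fat body genes were higher too (medians 0.78 and 0.63), while the storage genes were not (medians -0.29 and -0.04). The former are sex-biased as well, and the sex of the flies was not stated, so they do not mark fat body alone. Male-biased genes had medians of -0.33 at 18 °C and -0.19 at 29 °C (camera adjusted p = 0.498 and 0.294). The 19 genes of both fat body lists had a median below the immune median by more than 2 SE. The difference was -1.20 (SE 0.306) at 18 °C and -1.26 (SE 0.603) at 29 °C. That SE resamples genes as if they were independent and does not measure the spread between libraries. Differences of strain or culture between the 1 knockdown and the 1 control line cannot be told apart from the knockdown, since either would give those 21 genes. An effect of BEAF-32 depletion on immune gene expression may therefore be proposed only as a hypothesis, to be tested in further lines.

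Of 66 respiratory chain genes all had a positive interaction value, but 3 were called, and with an estimated correlation the list did not stand apart from other genes (adjusted p = 0.489). A change in muscle share is argued against in these libraries, since the muscle list had a median interaction of -0.0223 (quartiles -0.132 and 0.091). The difference from the respiratory chain was -0.385. Its SE of 0.052 resamples genes as if they were independent and does not measure the spread between libraries. Thinning all libraries to the lowest total left a median of 0.359, but thinning hardly alters the expected ratios of abundant genes and so cannot decide on depth. A single library is argued against by the lowest median with any one left out, 0.293 without control 18 °C replicate 3, where the 3 calls were lost. A difference between the lines and an effect of BEAF-32 depletion both stay open and cannot be told apart here, since each genotype was a single line.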

How the results depend on the processing

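Leaving out sets of libraries and collapsing near-identical genes were chosen only after the result was seen. BEAF-32 kept its direction and call under every alternative run (-4.04 to -3.46 at 18 °C and -4.29 to -3.66 at 29 °C with single libraries left out). Requiring a 2-fold change left 660, 655, 297, 269, 73 and 625 genes for temperature in control flies, in knockdown flies, knockdown at 18 °C, at 29 °C, the interaction and temperature over both genotypes, by construction. Without the filter the interaction gave 423 genes against 209; the cause was not tested. Without the 3 libraries high in odorant-binding genes the counts that moved by over 1.5 times were 1854, 559 and 80 for temperature in knockdown flies, knockdown at 18 °C and the interaction, of which 1746, 521 and 61 were also called with all libraries; this setting keeps fewer samples. With an estimated correlation 3 list calls stood, against 50 by the preset one. Of H3K4me3 peaks 1906 were shared among the stronger part of each list by score and 2828 by midpoints within 200 bp, against 4360. Single libraries left out gave 2948 to 3514, 2665 to 3247, 972 to 1281, 873 to 1395, 122 to 250 and 4238 to 4352 genes in the order above, 903 to 962 raised in both genotypes and 446 to 513 changed by knockdown at both temperatures. The response difference ran from -0.017 to 0.0308 for raised genes and from -0.00517 to 0.0286 for lowered genes, the last called by limma's fry without control 18 °C replicate 2; both medians crossed 0. The low counts were without control 29 °C replicate 3 (873 and 122) and knockdown 29 °C replicate 3 (138). DESeq2 gave 2828, 2613, 1009, 988, 215 and 3917 genes, thinning 2787, 2661, 1038, 944, 163 and 3804. The replicate numbers do not pair the libraries (same-number correlations -0.113 to 0.027, and 0 of 12 libraries correlated best with their own number); the replicate block gave 3368, 3099, 1178, 1225, 173 and 4445 genes and 51 list calls, the clock list joining for the interaction (adjusted p = 0.0453). Scaling moved the median of all genes by less than 0.1. Of 473 calls of named genes 374 held under every setting in which the gene was tested, 99 were lost under at least 1 and 0 reversed. The settings with a fold minimum, with sets of libraries left out or with near-identical genes collapsed were not part of this count. The promoter motif tests, with their alternatives, and the assignment of peaks to genes were not run. On simulated counts 25.4% of interactions of 1.5-fold were recovered, so many interactions of that size may have been missed, and the cause was not tested.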

Other observations

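No test in this part was chosen only after the result was seen. Some fixed lists were not described above for 29 °C against 18 °C in control flies. Of 8 visible marker genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.667, upward, with a median of 0.14 and a mean of -0.10), with v and bw 1.96-fold and 1.99-fold higher. Of 34 odorant-binding genes 11 rose and 14 fell (12 and 15 adjusted over the list alone; camera adjusted p = 0.455, downward, while the median was 0.25 and the mean 0.65), and 7 rose without control 29 °C replicate 1. Obp99a was among the lowered ones, falling 12.3-fold from 915 ± 306 to 74.5 ± 19.6 CPM.

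Few markers of gut, ovary and accessory gland were measured in these heads, with 1, 3 and 6 genes. Of the ovary and eggshell genes 1 rose and 1 fell in control flies (1 and 1 adjusted over the list alone; camera adjusted p = 0.706), where Cp19 kept its call only without control 18 °C replicate 2 or knockdown 18 °C replicates 1 or 3, and without any other library its edgeR adjusted p was 0.0502 to 0.176; DESeq2 gave 0.0692. Again 1 rose and 1 fell with warmth in knockdown flies (1 and 1 adjusted over the list alone; camera adjusted p = 0.971, downward, with a median of 0.11 and a mean of -0.07). The chorion gene Cp19 fell from 4.41 ± 1.8 to 0.374 ± 0.114 CPM, and Cp18, with 2 counts over the knockdown libraries at 18 °C and 26 at 29 °C, had a ratio of 9.52 with a counting interval of 2.38 to 82.8. Of 6 accessory gland and testis genes 2 rose with warmth in control flies and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.432), janB losing its call without control 29 °C replicate 1 (edgeR adjusted p = 0.0717); the abundant member Acp1 is a cuticle protein caught by its name. Larval storage protein genes behaved apart from each other: Lsp1beta was higher at 29 °C in both genotypes, while Lsp2 fell 12.1-fold in control flies.

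The yellow gene had 2.36 ± 0.487 and 0.646 ± 0.389 CPM in control flies at 18 °C and 29 °C. In knockdown flies it had 4.18 ± 0.811 and 19.6 ± 4.15 CPM. It is on the list of genetic background and visible marker genes, and a difference of line cannot be told apart from the knockdown. The long noncoding RNA CR45680 stood at 0.5405 ± 0.00402 and 10.35 ± 1.4 CPM in control and knockdown flies at 18 °C (edgeR adjusted p = 4.7e-08). CG9150 fell 5.9-fold with knockdown at 18 °C, from 27.8 ± 3.37 to 4.77 ± 1.01 CPM.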
